A study of Mus musculus with 8 samples.

How the data were processed

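RNA was sequenced from plasma cells sorted from the bone marrow of C57BL/6 mice by a Blimp1-GFP reporter and surface CD138, per the labels. The 8 libraries comprise 4 from wild-type mice (WT), 2 labelled as Blimp1 knockout (Blimp1KO) and 2 labelled as Xbp1 knockout (Xbp1KO). The labels place WT replicates 1 and 2 and both Blimp1KO libraries in batch 1, and WT replicates 3 and 4 and both Xbp1KO libraries in batch 2. The series design text calls the replicates biological. RNA was extracted with an RNeasy Micro kit and libraries were made with a TruSeq RNA kit, per the labels' protocols. Sequencing depth, read length, the strand setting of the counting and the exons deleted in either knockout are not stated in these sources.

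Subread, featureCounts and limma are named as processing tools, per the labels, without versions or the step each was used for. The mouse builds GRCm38 and mm10, which are names of the same assembly, are also named there. The deposited series table holds raw read counts per Entrez gene for all 8 libraries, per the file headers, and its values are whole numbers with no normalization. The deposited per-sample files hold log2 FPKM, a count scaled by gene length and library size, per the file headers, for 13945 genes, of which the J chain gene is the 1 immunoglobulin gene. The gene filter and library scaling behind these FPKM values are not stated. All results below were computed from the counts, and the FPKM served as an alternative.

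Gene symbols came from the deposited per-sample files for 13860 of the 27179 Entrez identifiers and from the RefSeq gene table of GRCm38.p6 for a further 11720, while 1599 had no symbol. Counts of genes without a symbol made up 0.057% to 0.240% of each library. Positions are those of GRCm38.p6 in the RefSeq table.

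Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at its minimum count of 10, which left 15073 genes, and library sizes were scaled by TMM, with factors from 0.564 to 2.11. CPM values are computed on these scaled library sizes. A quasi-likelihood negative binomial model with a mean for each of the 4 groups was fitted to all 8 libraries, with 4 residual degrees of freedom and 3.06 prior degrees of freedom. The contrasts were Blimp1KO minus WT of batch 1, Xbp1KO minus WT of batch 2, the difference between these 2 effects, and WT of batch 2 minus WT of batch 1. Every p-value on a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene was called changed at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Immunoglobulin shares were computed on the raw counts of the 261 immunoglobulin genes in the table, J chain included, and compared by an exact 2-sided permutation test.

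The design, the gene lists, the alternatives and the rule for named genes were set before the data were examined, apart from the alternatives named below as added. Genes named in the text are Prdm1, Xbp1 and Sdc1; the 8 highest and 8 lowest log2 fold changes of each knockout among called genes with an average log2 CPM of at least 3 and no overlap between the knockout libraries and WT libraries of the batch, without immunoglobulin segments, pseudogenes and predicted genes; up to 4 called members per list with the smallest p, or up to 2 as values where none was called; and the 5 highest and 5 lowest of the difference of effects. A few genes that this rule selects are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

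The 27 fixed lists were UPR transducers and transcription factors, ATF4 integrated stress response targets, ER chaperones and oxidative folding, ER-associated degradation, ER translocation and signal peptide processing, N-glycosylation, ER-Golgi vesicle transport, immunoglobulin constant regions and J chain, immunoglobulin mRNA processing factors, amino acid transport and mTORC1, mature B cell identity, MHC class II antigen presentation, plasma cell identity and surface, BCL2 family and apoptosis, proliferation, sterol and fatty acid synthesis, RIDD substrates (mRNAs cut by the stress sensor IRE1), interferon-stimulated genes, ribosomal proteins, mitochondrial oxidative phosphorylation, proteasome, and markers of 6 other kinds of cell that bone marrow holds: neutrophils and monocytes, erythroid cells and megakaryocytes, T and NK cells, dendritic cells, stroma and endothelium, and B progenitors. Each list was tested with limma's camera (limma 3.58.1) on voom values at a preset correlation between genes of 0.01, then with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the 27 lists of a contrast. Counts of called list members are given over all genes tested and adjusted over the list alone.

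The fit was tested on simulated counts drawn from the means and dispersions of these libraries. In the Blimp1KO contrast, over 13981 genes that passed the filter, it recovered 53 of 100 genes changed 4-fold and 3 of 100 changed 2-fold, with 9 unchanged genes among 65 calls. In the Xbp1KO contrast it recovered 51 of 100 changed 4-fold and 8 of 100 changed 2-fold, with 7 unchanged genes among 69 calls, also over 13981 genes. A planted list in the simulated Xbp1KO contrast had an adjusted p of 2.26e-27 at the preset correlation and 0.00706 with an estimated correlation, and 0 of 26 random lists were called by either. Simulated genes were drawn independently of each other, so this does not test the preset on lists whose genes vary together. In the measured Blimp1KO contrast the estimated correlation was 0.624 for proliferation and 0.769 for ribosomal proteins.

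Pearson's r of log2 CPM across genes between replicates was 0.983 for WT of batch 1, 0.972 for Blimp1KO, 0.950 for WT of batch 2 and 0.926 for Xbp1KO. Across genes, the deposited FPKM of WT replicate 1 tracked the counts of WT replicate 2 best (r 0.99966, against 0.97774 for the count column of its own number), and the reverse held too. Both Blimp1KO replicates crossed in the same way. Group membership is unaffected, and the numbers below are those of the count table.

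The alternatives were edgeR's RLE scaling, no filter beyond a total above 0 (23678 genes), a filter of at least 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, a test against a fold change of 1.5 with glmTreat, removal of all immunoglobulin genes, each library left out in turn, fits of each batch alone, all 4 WT libraries pooled without a batch term, and the replicate number as a block in batch 1. The planned use of counts from the per-sample files was replaced by limma-trend on their log2 FPKM, since those files hold no counts. A pair of settings was added after the data were seen: WT replicate 4 and Xbp1KO replicate 2 left out together, because of their neutrophil and erythroid transcripts, and a replicate block in both batches.

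Some genes share reads with others. Immunoglobulin segments and constant regions, alpha and beta globins, MHC class II genes and ribosomal proteins with processed pseudogenes have near-identical copies, and their single values are uncertain. Of 135 named genes, 130 were found in the GENCODE annotation of the build, and 38 of them overlapped an exon of another gene. The overlap reached 20% of exon bases in 4: Bloc1s1, Gmppb, Itgam and Srprb. Without a stated strand setting, reads of a gene and of its antisense partner cannot be told apart.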

Results

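The mouse plasma cell transcriptome was measured in 4 groups of 2 libraries. The design asks what 2 transcription factors, Blimp1 and XBP1, maintain in antibody-secreting cells of the bone marrow: WT of batch 1 serves Blimp1KO and WT of batch 2 serves Xbp1KO. Total counts were 78.3 M and 78.9 M (M for 1e6) in WT replicates 1 and 2 and 69.2 M and 78.5 M in the Blimp1KO libraries. They were 145.41 M and 73.4 M in WT replicates 3 and 4, and 104 M and 44.012 M in the Xbp1KO libraries. Counts outside immunoglobulin genes ranged from 19.0 M in WT replicate 1 to 72.9 M in Xbp1KO replicate 1. The leading principal component of log2 CPM held 45.6% of the variance, with all batch 1 libraries between -83.1 and -61.2 and all batch 2 libraries between 46.5 and 107. By the design set in advance, each knockout was compared with WT of its own batch, with pooled WT as an alternative.

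The targeted genes were measured before any other. Prdm1, which encodes Blimp1 (Entrez 12142, chromosome 10, 44437174 to 44528558 in GRCm38.p6), had 301 and 306 CPM in WT of batch 1, 243 and 176 CPM in Blimp1KO, 260 and 237 CPM in WT of batch 2, and 447 and 322 CPM in Xbp1KO. Its log2 fold change was -0.54 ± 0.25 (SE, n = 2 per group, adjusted p = 0.401) in Blimp1KO and 0.63 ± 0.25 (adjusted p = 0.180) in Xbp1KO. Xbp1 (Entrez 22433, chromosome 11, 5520641 to 5525993) had 3005 and 3008 CPM in WT of batch 1, 1371 and 1671 CPM in Blimp1KO, 2129 and 2203 CPM in WT of batch 2, and 1302 and 1105 CPM in Xbp1KO. Its log2 fold change was -0.98 ± 0.25 (adjusted p = 0.141) in Blimp1KO and -0.85 ± 0.25 (adjusted p = 0.0939) in Xbp1KO. Counts over a whole gene include reads outside a deleted part, and the reporter sits in Prdm1, so neither gene's level tests the genotype labels. Sdc1, which encodes the sort marker CD138, had log2 fold changes of -0.52 ± 0.22 (adjusted p = 0.361) in Blimp1KO and 0.74 ± 0.22 (adjusted p = 0.0980) in Xbp1KO.

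Immunoglobulin genes took 75.7% ± 0.0750 of all counts (SD, n = 2) in WT of batch 1 and 56.9% ± 2.07 in Blimp1KO, a difference of -18.8 percentage points. They took 67.3% ± 3.46 in WT of batch 2 and 27.6% ± 3.38 in Xbp1KO, a difference of -39.7 percentage points. Both differences exceeded the spread between replicates, but the exact 2-sided permutation p of 0.333 in each case is the smallest that 2 against 2 libraries allow. Ighm, the heavy chain of IgM, took 14.5% ± 6.75 and 3.1015% ± 0.994 of counts in WT of batch 1 and Blimp1KO, and 14.0% ± 0.693 and 1.33% ± 0.0260 in WT of batch 2 and Xbp1KO. Igha, the heavy chain of IgA, took 8.66% ± 3.66 and 7.78% ± 2.38 in batch 1, and 5.13% ± 0.160 and 0.754% ± 0.295 in batch 2. Igkc, the kappa constant region, took 16.6% ± 0.866 and 13.6% ± 2.40 in batch 1, and 13.8% ± 2.15 and 7.45% ± 1.51 in batch 2. The J chain, which joins the units of secreted IgM and IgA, took 6.29% ± 0.0407 and 6.15% ± 0.503 in batch 1, and 4.67% ± 0.529 and 6.32% ± 0.281 in batch 2.

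**Figure D1:**
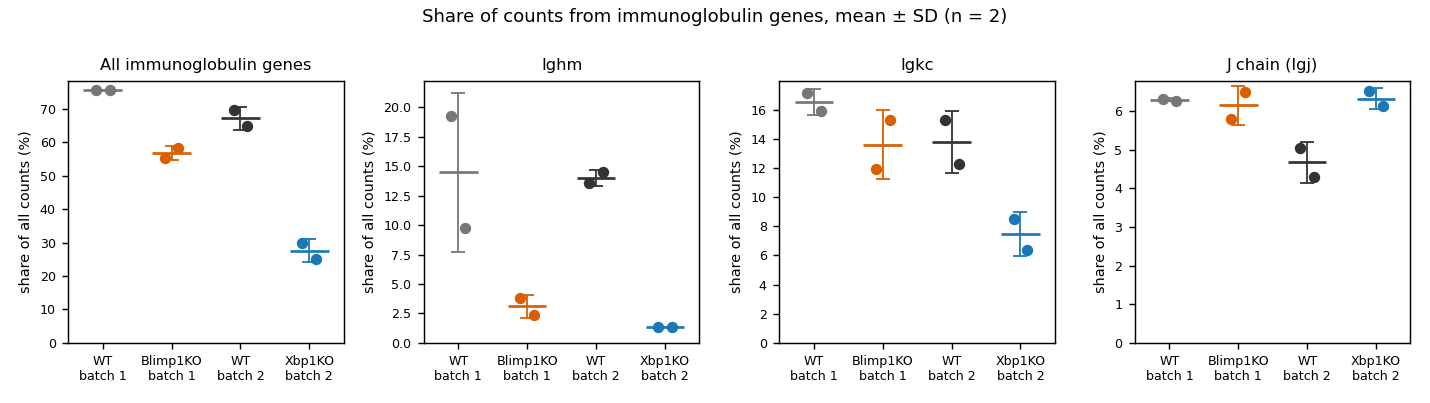
Share of all counts, in percent, taken by all immunoglobulin genes, Ighm, Igkc and the J chain gene in each library (points), with the group mean and SD (bars, n = 2). The mean share of all immunoglobulin genes was 75.7% in WT of batch 1 against 56.9% in Blimp1KO, and 67.3% in WT of batch 2 against 27.6% in Xbp1KO.

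Genes of antigen presentation and of the B cell stage were higher in Blimp1KO than in WT of batch 1. Spib, a transcription factor of B cells, went from 6.50 ± 1.02 to 177 ± 28.9 CPM (SD, n = 2), a log2 fold change of 4.77 ± 0.62 (SE, adjusted p = 0.0326). Ltb, which encodes lymphotoxin beta, rose by 3.90 ± 0.34 (adjusted p = 0.0174), and Ly86, a partner of the receptor RP105 on B cells, by 3.03 ± 0.41 (adjusted p = 0.0338). H2-Aa, the alpha chain of the class II molecule I-A, rose by 2.999 ± 0.36, from 316 ± 115 to 2522 ± 415 CPM (adjusted p = 0.0320). In all, 130 of 15073 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 87 higher and 43 lower in Blimp1KO. The others among the 8 highest were H2-DMb2 at 4.05 ± 0.63, the retinol dehydrogenase gene Rdh12 at 3.72 ± 0.23, Plac8 at 3.62 ± 0.38, Map3k15 at 3.37 ± 0.53 and Pigr, which encodes the receptor that carries polymeric IgA and IgM across epithelia, at 3.37 ± 0.43. The 8 lowest were Chac1, a glutathione-degrading enzyme of the stress response, at -2.18 ± 0.33 (adjusted p = 0.0392), the insulin signalling adaptor Irs2 at -2.16 ± 0.35 (adjusted p = 0.04998), the linker histone Hist1h1c at -1.99 ± 0.26, the cortisone reductase gene Hsd11b1 at -1.87 ± 0.30, Clec2g at -1.85 ± 0.20, Gadd45b at -1.79 ± 0.17, the thrombomodulin gene Thbd at -1.78 ± 0.22 and Lrrn3 at -1.75 ± 0.24. The count of 130 varied with the library left out. All 130 genes kept the sign of their log2 fold change with a batch 1 library left out, in fits that share most libraries. Batch 2 libraries act on this contrast through the gene filter, the scaling and the spread shared by all groups. They do not enter the group means behind these signs, so leaving them out does not test the signs. EdgeR called 0 genes without WT replicate 1 and 0 without WT replicate 2 (1160 and 1064 at an unadjusted p below 0.05), 3 without WT replicate 3, 3 without WT replicate 4, 688 without Blimp1KO replicate 1 and 230 without Blimp1KO replicate 2. The fit of batch 1 alone called 20 genes, all higher and 0 lower, of which 10 were among the 130. Of the 16 genes named here as the 8 highest and 8 lowest it called Spib, Ltb, Ly86 and Rdh12 alone, and it did not call H2-Aa. The count was 517 by edgeR without the filter and 813 by DESeq2, also without the filter (23678 genes).

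**Figure D2:**
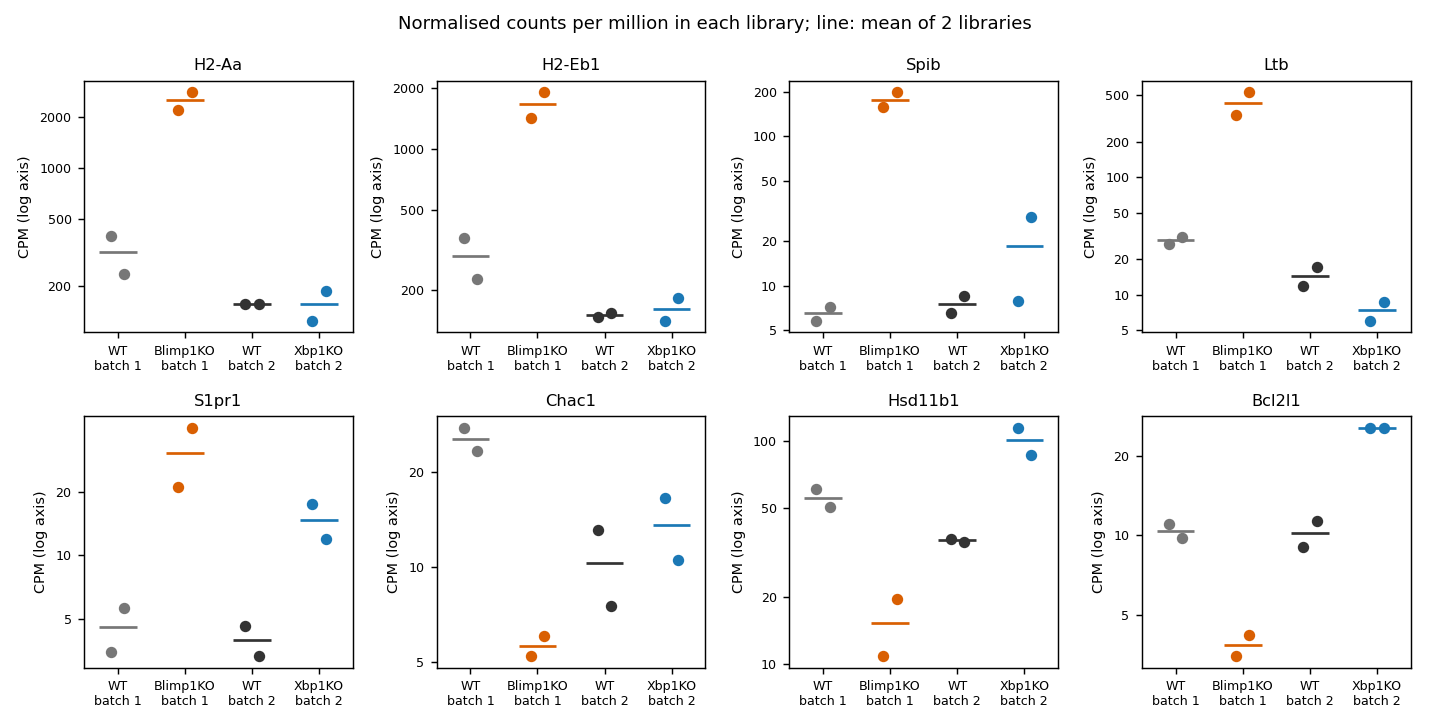
Normalised CPM of 8 genes in each library (points, log axis) with the mean of each group of 2 (lines). H2-Aa rose from a mean of 316 CPM in WT of batch 1 to 2522 CPM in Blimp1KO, and Bcl2l1 went from 10.4 to 3.86 CPM.

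Of the 12 tested members of MHC class II antigen presentation, 7 rose in Blimp1KO, 0 fell and 5 did not pass, or 11 rose adjusted over the list alone. The 4 with the smallest p were H2-Ob (2.51 ± 0.27), H2-Aa (2.999 ± 0.36), H2-DMa (1.72 ± 0.21) and H2-Eb1 (2.50 ± 0.32). The list's median log2 fold change was 2.04, with a camera adjusted p of 4.83e-17, adjusted p = 0.211 with an estimated correlation, and 0.0258 by fry. Dendritic cell markers, from cells rich in class II, had a median of 0.76 and 11 of 14 estimates higher. Of these 14, 0 passed by either adjustment, and fry's adjusted p was 0.346. Whether they moved together with class II genes was not tested. Of 35 members of mature B cell identity, 4 rose, among them Spib, Ly86 and the costimulatory receptor Cd40 (1.71 ± 0.27), and 15 rose and 2 fell adjusted over the list alone. That list's median was 0.953 (camera adjusted p = 9.75e-08, adjusted p = 0.211 with an estimated correlation, and 0.0729 by fry). Without WT replicate 1, 2, 3 or 4, 0 members of either list passed, with medians from 1.68 to 2.47 for class II and from 0.912 to 1.13 for B cell genes. WT replicates 3 and 4, of batch 2, act on this contrast only through the shared spread, the filter and the scaling. The fit of batch 1 alone called 0 class II and 5 B cell genes. Without Blimp1KO replicate 1, 8 class II and 9 B cell genes passed, and 9 B cell genes passed without Xbp1KO replicate 1 and without Xbp1KO replicate 2. With WT replicate 4 and Xbp1KO replicate 2 both left out, 0 class II and 7 B cell genes passed.

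Genes of protein secretion had lower estimates in Blimp1KO, each list by camera and none by single genes. In ER chaperones and oxidative folding, 0 of 29 members passed (1 higher and 3 lower adjusted over the list alone), with values of -1.58 ± 0.29 for Txndc5 and -1.09 ± 0.25 for Creld2. The list's median was -0.31 (camera adjusted p = 2.06e-05, adjusted p = 0.410 with an estimated correlation). In ER-associated degradation, 0 of 21 passed (2 lower adjusted over the list alone), with -0.88 ± 0.19 for Syvn1 and -1.06 ± 0.26 for Edem1. The median was -0.45 (adjusted p = 2.90e-08, adjusted p = 0.337 with an estimated correlation). In ER translocation and signal peptide processing, 0 of 24 passed, 0 also adjusted over the list alone, with -1.29 ± 0.32 for Tram2 and -0.70 ± 0.19 for Srprb. The median was -0.35 (adjusted p = 1.11e-06, adjusted p = 0.337 with an estimated correlation). In N-glycosylation, 0 of 30 passed by either adjustment, with -0.81 ± 0.17 for Alg6 and -0.59 ± 0.15 for Mogs. The median was -0.43 (adjusted p = 2.30e-07, adjusted p = 0.364 with an estimated correlation). In ER-Golgi vesicle transport, 0 of 40 passed by either adjustment, with -0.77 ± 0.18 for Lman1 and -0.76 ± 0.18 for Sec24d. The median was -0.33 (adjusted p = 1.10e-08, adjusted p = 0.337 with an estimated correlation). Among immunoglobulin constant regions and J chain, 0 of 13 passed (4 lower adjusted over the list alone), with -3.08 ± 0.59 for Ighd and -3.05 ± 0.59 for Ighm. The median was -1.01 (adjusted p = 2.90e-08, adjusted p = 0.211 with an estimated correlation). Fry's adjusted p was 0.0258 for this immunoglobulin list. It was 0.117 for ER chaperones, 0.0729 for degradation, 0.0966 for translocation, 0.105 for N-glycosylation and 0.0739 for vesicle transport. Over all genes tested, 2093 had an unadjusted p below 0.05 by edgeR in Blimp1KO and limma-voom called 83, while DESeq2, run without the filter on 23678 genes, called 813.

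Chac1 was the 1 of 18 ATF4 integrated stress response targets that fell (1 higher and 3 lower adjusted over the list alone), with a list median of -0.46 (camera adjusted p = 0.0165, adjusted p = 0.387 with an estimated correlation, and 0.132 at the preset correlation without WT replicate 1, 0.0555 without Blimp1KO replicate 1 and 0.0628 without Blimp1KO replicate 2). Of 13 UPR transducers and transcription factors, 0 passed by either adjustment, with -0.98 ± 0.25 for Xbp1 and -0.68 ± 0.18 for Atf4. The median was -0.13 (adjusted p = 0.0103, adjusted p = 0.387 with an estimated correlation, and 0.0963 at the preset correlation without Blimp1KO replicate 2). Of 25 members of amino acid transport and mTORC1, 0 passed (1 higher and 3 lower adjusted over the list alone), with -1.91 ± 0.38 for Slc3a2 and 1.45 ± 0.30 for Ddit4. The median was -0.27 (adjusted p = 0.00631, adjusted p = 0.337 with an estimated correlation, and 0.0828 at the preset correlation without Blimp1KO replicate 2). Of 26 members of BCL2 family and apoptosis, Bcl2l1, which encodes the survival protein BCL-XL, fell by 1.43 ± 0.18 (adjusted p = 0.0324), the 1 call by either adjustment. Its list had a median of 0.18 with a camera adjusted p of 0.0496, which was 0.0939 without WT replicate 2, 0.0523 without WT replicate 3, 0.0532 without WT replicate 4, 0.108 without Blimp1KO replicate 1 and 0.0963 without Blimp1KO replicate 2, and adjusted p = 0.337 with an estimated correlation. Of 30 proliferation genes 0 passed by either adjustment, with -1.09 ± 0.26 for Top2a and -0.99 ± 0.26 for Bub1. The median was -0.54 (adjusted p = 0.000843, adjusted p = 0.637 with an estimated correlation, and 0.163 and 0.134 at the preset correlation without WT replicate 2 and without Blimp1KO replicate 1). Ribosomal proteins had higher estimates for 83 of 85 genes and 0 past the test by either adjustment, with 0.92 ± 0.23 for Rpl27a and 0.53 ± 0.14 for Rpl7l1. The mean log2 CPM of ribosomal proteins was 4.599 and 4.625 in WT of batch 1, 4.776 in Blimp1KO replicate 1 and 5.636 in Blimp1KO replicate 2, and their median log2 fold change was 0.11 without Blimp1KO replicate 2 and 1.10 without Blimp1KO replicate 1. Their median was 0.66 (adjusted p = 1.33e-17, adjusted p = 0.410 with an estimated correlation). By fry the adjusted p of the lists in this paragraph lay from 0.0966 (BCL2 family) to 0.482 (proliferation), with 0.293 for ribosomal proteins.

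The other lists gave no camera call in Blimp1KO apart from dendritic cell markers, and the single calls of S1pr1, Scd1 and Alpl, like those of Chac1 and Bcl2l1, ended without WT replicate 1, 2, 3 or 4. Chac1 also lost its call without Blimp1KO replicate 1 and without Blimp1KO replicate 2, and S1pr1 without Blimp1KO replicate 2. Among 27 genes of plasma cell identity and surface, S1pr1, a receptor that guides cell exit into blood, rose by 2.75 ± 0.41 (adjusted p = 0.0382), with 2 higher and 3 lower adjusted over the list alone and a camera adjusted p of 0.369. In sterol and fatty acid synthesis, the desaturase Scd1 rose by 2.12 ± 0.24, the 1 of 28 called by either adjustment (camera adjusted p = 0.172). Among immunoglobulin mRNA processing factors 0 of 9 passed by either adjustment (Ell2 -0.78 ± 0.28, Hnrnpf 0.27 ± 0.14), with a median of 0.06 against camera's downward direction (adjusted p = 0.994). RIDD substrates had 0 of 6 (Hgsnat -0.24 ± 0.30, Sparc -0.84 ± 1.31, camera adjusted p = 0.978) and interferon-stimulated genes 0 of 25 by either adjustment (Irf9 0.45 ± 0.14, Isg20 -0.74 ± 0.24), with a median of -0.000215 against camera's upward direction (adjusted p = 0.994). Mitochondrial oxidative phosphorylation had 0 of 73 (Uqcrh 0.54 ± 0.29, Ndufs1 -0.26 ± 0.17) and the proteasome 0 of 38 by either adjustment (Psmd3 -0.35 ± 0.16, Psmd10 0.38 ± 0.20), each with a camera adjusted p of 0.994. The oxidative phosphorylation median of 0.02 went against camera's downward direction.

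Markers of other cells in Blimp1KO were tested beside these groups. Dendritic markers had a median of 0.76 with 0 of 14 past the test by either adjustment (Zbtb46 2.21 ± 0.75, Klk1 3.25 ± 1.14, camera adjusted p = 0.0439, adjusted p = 0.364 with an estimated correlation). That camera call ended without WT replicate 2 (adjusted p = 0.0939) and without Blimp1KO replicate 1 (adjusted p = 0.163). Neutrophil and monocyte markers had 0 of 24 (1 higher adjusted over the list alone), with 1.90 ± 0.32 for Itgam and -2.28 ± 1.84 for Mmp9, and their median of -0.58 went against camera's upward direction (adjusted p = 0.994). Erythroid and megakaryocyte markers had 0 of 16 by either adjustment (Itga2b -0.96 ± 0.61, Tfrc -1.01 ± 0.77, camera adjusted p = 0.775) and T and NK markers 0 of 22 (Tcf7 1.06 ± 0.33, Cd2 1.05 ± 0.50, camera adjusted p = 0.115). Of 13 stroma and endothelium markers the phosphatase Alpl fell by 1.61 ± 0.13 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.115). B progenitor markers had 0 of 13 (2 lower adjusted over the list alone), with -1.87 ± 0.30 for Kit and -1.07 ± 0.25 for Cd93 (camera adjusted p = 0.161).

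Genes of the secretory pathway and immunoglobulin transcripts were lower in Xbp1KO than in WT of batch 2, and a smaller set was higher. Hid1, a protein of secretory granule formation, fell by 5.30 ± 0.19 on the log2 scale (SE, n = 2 per group, adjusted p = 0.000231), from 131 ± 11.7 to 3.33 ± 0.198 CPM (SD). Dnajb9, a cochaperone of BiP in the ER, fell by 3.87 ± 0.18 (adjusted p = 0.000342), from 195 ± 12.2 to 13.3 ± 0.786 CPM. Ighm fell by 4.55 ± 0.63 (adjusted p = 0.00930). Tsc22d1, a leucine zipper regulator, rose by 4.31 ± 0.37 (adjusted p = 0.00247), and Slc7a3, a transporter of cationic amino acids, by 3.65 ± 0.25 (adjusted p = 0.00174). In all, 1160 of 15073 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 397 higher and 763 lower in Xbp1KO. The others among the 8 highest were the fatty acid receptor Cd36 at 3.21 ± 0.35, the sodium pump subunit Atp1b1 at 3.20 ± 0.51, the peptidase Dpp4 at 2.68 ± 0.28, Cox6a2 at 2.57 ± 0.50, the oxysterol receptor Gpr183 at 2.28 ± 0.32 and Gsto1 at 2.23 ± 0.21. The others among the 8 lowest were the potassium channel Kcnk6 at -4.18 ± 0.30, the ER prolyl isomerase Fkbp11 at -4.06 ± 0.34, Igha at -3.96 ± 0.60, Ighg2c at -3.90 ± 0.54 and the tubulin acetyltransferase Atat1 at -3.88 ± 0.15. The count of 1160 was 546 without WT replicate 1, 566 without WT replicate 2, 225 without WT replicate 3, 313 without WT replicate 4, 2123 without Blimp1KO replicate 2, 329 without Xbp1KO replicate 1 and 319 without Xbp1KO replicate 2, and 2172 by DESeq2 without the filter. All 1160 kept their sign with each of these libraries left out, in fits that share most libraries with the fit that picked them. Batch 1 libraries do not enter the group means behind these signs, so leaving them out does not test the signs. Without WT replicate 3, 11 of these 16 genes kept their call and Atp1b1, Cox6a2, Gpr183, Igha and Ighg2c lost it. Without WT replicate 4, Atp1b1, Cox6a2 and Gpr183 lost it. Atp1b1, Cox6a2, Gpr183, Igha and Ighm lost it without Xbp1KO replicate 1, and Cox6a2, Igha and Ighm without Xbp1KO replicate 2.

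**Figure D3:**
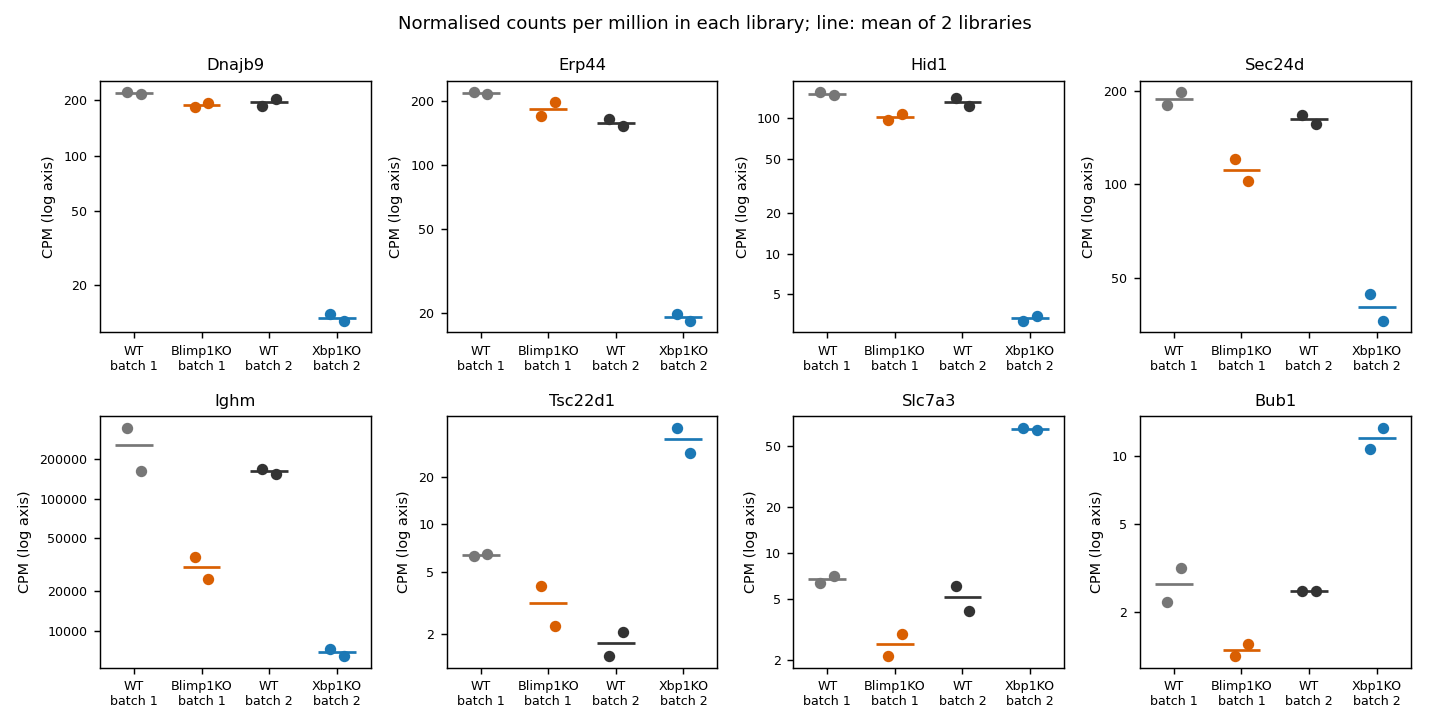
Normalised CPM of 8 genes in each library (points, log axis) with the mean of each group of 2 (lines). Hid1 went from a mean of 131 CPM in WT of batch 2 to 3.33 CPM in Xbp1KO, and Slc7a3 from 5.13 to 64.5 CPM.

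Transcripts of neutrophils and red cell precursors were higher in WT replicate 4 and Xbp1KO replicate 2 than in the other 2 libraries of batch 2. S100a8, a member of the neutrophil and monocyte list, had 0.461 and 102 CPM in WT replicates 3 and 4, and 0.337 and 192 CPM in Xbp1KO replicates 1 and 2. The globin Hba-a2 had 13.0, 112, 3.31 and 349 CPM in the same order. With both of these libraries left out, a setting added after these values were seen, all 1160 genes called in Xbp1KO from 8 libraries kept their sign. This setting leaves a lone library in each batch 2 group and shares its libraries with the fit that picked these genes. Fewer genes were then called, with counts given below. The Blimp1KO log2 fold changes rest on batch 1 libraries, so this setting does not test their sign.

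Of 29 ER chaperones and oxidative folding genes, 14 fell in Xbp1KO, 2 rose and 13 did not pass, or 17 fell and 4 rose adjusted over the list alone. Dnajb9, the thiol oxidoreductase Erp44 (-3.05 ± 0.18), the disulfide oxidase Ero1lb (-2.29 ± 0.17) and the cochaperone Dnajc3 (-2.78 ± 0.22) fell, while Hsp90b1 (1.62) and Ero1l (1.16), named after their values were seen, rose. The list's median was -1.10 (camera adjusted p = 3.60e-09, adjusted p = 0.488 with an estimated correlation). In ER translocation and signal peptide processing, 13 of 24 fell and 0 rose (18 fell adjusted over the list alone), among them the signal recognition receptor Srpr (-1.59 ± 0.18), the channel subunits Sec61a1 (-1.68 ± 0.22) and Sec61b (-2.15 ± 0.28), and Ssr3 (-1.55 ± 0.21). Its median was -1.05 (adjusted p = 8.37e-11, adjusted p = 0.462 with an estimated correlation). In N-glycosylation, 12 of 30 fell and 0 rose (16 fell and 2 rose adjusted over the list alone), among them the oligosaccharyltransferase subunits Rpn1 (-2.64 ± 0.24) and Magt1 (-2.08 ± 0.19), Gmppb (-1.56 ± 0.18, 33.6% of its exon bases shared with Rnf123 on the opposite strand) and Dpagt1 (-1.504 ± 0.19). Its median was -0.61 (adjusted p = 3.20e-08, adjusted p = 0.488 with an estimated correlation). In ER-Golgi vesicle transport, 15 of 40 fell and 0 rose (23 fell adjusted over the list alone), among them Bet1 (-1.81 ± 0.16), the coat subunit Sec24d (-2.003 ± 0.19), the cargo receptor subunit Mcfd2 (-1.52 ± 0.15) and the retrieval receptor Kdelr3 (-1.97 ± 0.19). Its median was -0.73 (adjusted p = 1.97e-12, adjusted p = 0.462 with an estimated correlation). In ER-associated degradation, 6 of 21 fell and 0 rose (10 fell adjusted over the list alone), among them Vimp (-1.27 ± 0.16), Ube2g2 (-0.82 ± 0.12), Edem2 (-1.66 ± 0.25) and Derl3 (-1.46 ± 0.25). Its median was -0.55 (adjusted p = 1.44e-06, adjusted p = 0.488 with an estimated correlation). Fry's adjusted p was 0.0052 for ER chaperones, translocation and vesicle transport, 0.0178 for N-glycosylation and 0.018 for degradation.

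These counts depended on the libraries. The 2 ER chaperones that rose numbered 0 without WT replicate 1, 2, 3 or 4, 0 without Xbp1KO replicate 1, 1 without Xbp1KO replicate 2 and 0 with WT replicate 4 and Xbp1KO replicate 2 both left out. ER chaperones that fell numbered 8 without WT replicate 3, 9 without WT replicate 4, 8 without Xbp1KO replicate 1 and 8 without Xbp1KO replicate 2, and translocation genes 0, 3, 4 and 0 in the same order. N-glycosylation genes that fell numbered 3, 5, 5 and 3, vesicle transport genes 6, 7, 7 and 7, and degradation genes 0, 1, 1 and 0. Without WT replicate 1, and equally without WT replicate 2, 7 N-glycosylation genes, 8 vesicle transport genes and 4 degradation genes fell. Without Blimp1KO replicate 2, 24 vesicle transport and 9 degradation genes fell. With WT replicate 4 and Xbp1KO replicate 2 both left out, 2 ER chaperones fell and 0 genes of the other 4 lists passed, while the medians stayed negative: -0.876 for ER chaperones, -1.06 for translocation, -0.617 for N-glycosylation, -0.703 for vesicle transport and -0.528 for degradation.

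**Figure D4:**
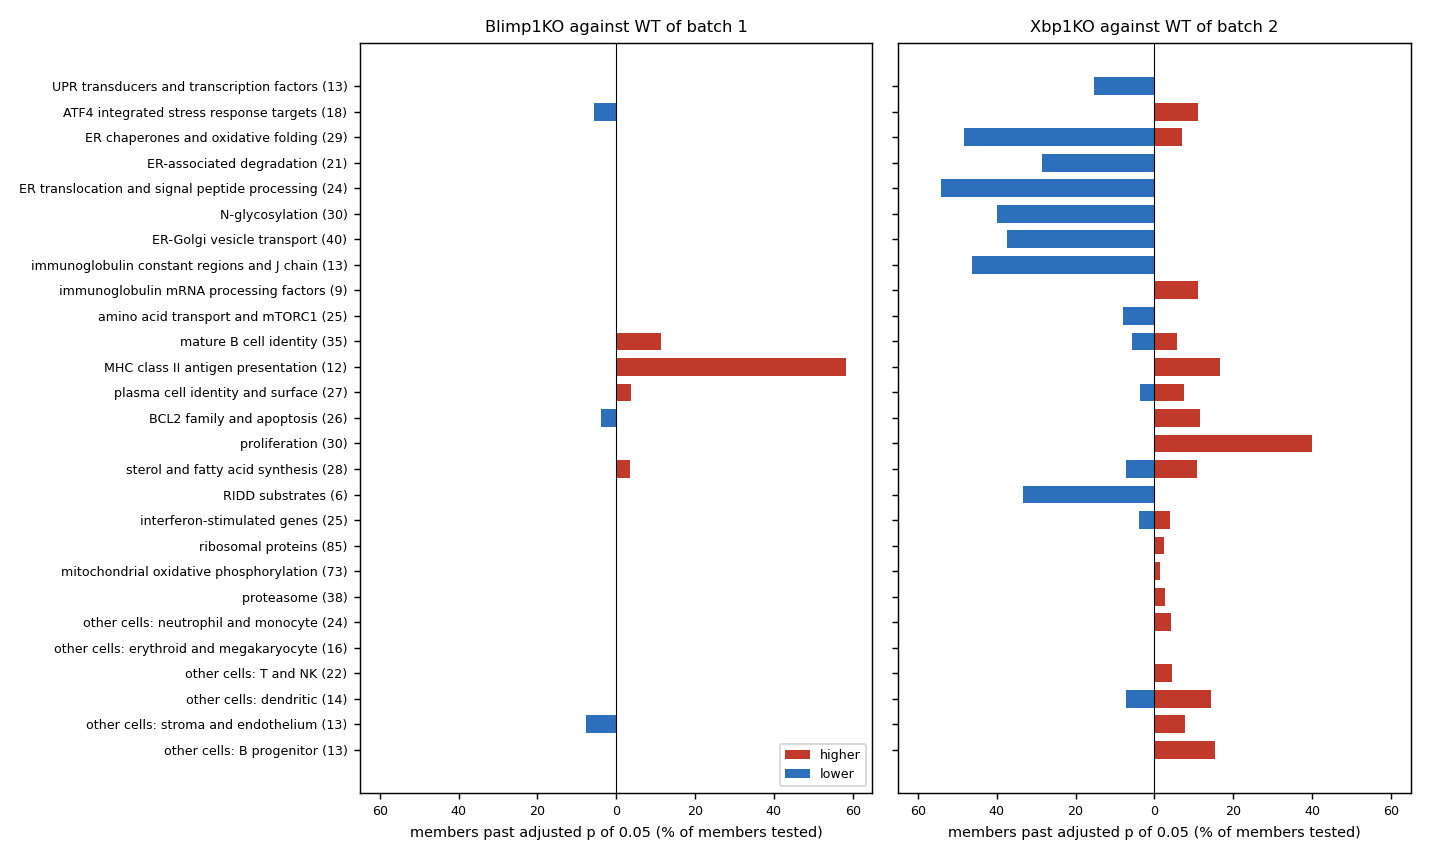
Percent of the tested members of each fixed list that passed edgeR's test, higher (red, to the right) or lower (blue, to the left) than WT of the batch, with the number of members in brackets, for Blimp1KO and Xbp1KO. In Blimp1KO 7 of 12 MHC class II genes rose, and in Xbp1KO 13 of 24 genes of ER translocation fell.

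Immunoglobulin genes made up 124 of the 763 genes lower in Xbp1KO, and 0 of the 257 tested rose. Of 13 immunoglobulin constant regions and J chain, 6 fell and 0 rose (9 fell adjusted over the list alone), among them Ighg1 (-3.56 ± 0.38), Ighm, Ighg2c and Igha. Fry gave this list an adjusted p of 0.0052. The list's median was -2.76 (camera adjusted p = 1.12e-07, adjusted p = 0.462 with an estimated correlation), and 2 fell without WT replicate 3, 4 without WT replicate 4, 2 without Xbp1KO replicate 1, 2 without Xbp1KO replicate 2 and 0 with WT replicate 4 and Xbp1KO replicate 2 both left out (median -2.01). Of 118 heavy chain variable segments tested, 83 fell in Xbp1KO, and of 102 kappa variable segments 29 fell. Without WT replicate 3 these numbers were 50 and 11, without WT replicate 4 57 and 17, without Xbp1KO replicate 1 49 and 14, without Xbp1KO replicate 2 43 and 10, and with WT replicate 4 and Xbp1KO replicate 2 both left out 22 and 1. In Blimp1KO, 4 heavy chain and 0 kappa variable segments fell by edgeR's test, and DESeq2 called 47 and 27. Segments share reads with near-identical neighbours and follow the clones in each mouse.

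Proliferation genes moved the other way: 12 of 30 rose in Xbp1KO and 0 fell (20 rose adjusted over the list alone), among them the mitotic checkpoint kinase Bub1 (2.28 ± 0.26), Myc (0.88 ± 0.13), the spindle motor Kif11 (1.74 ± 0.27) and the replicative helicase subunit Mcm4 (1.13 ± 0.18). The median was 1.16 (camera adjusted p = 8.37e-11, adjusted p = 0.488 with an estimated correlation, and 0.0498 by fry). Erythroid and B progenitor markers, from marrow cells that divide, had medians of 1.49 and 1.42, which were -3.70 and 0.0596 without Xbp1KO replicate 2. The number that rose was 5 without WT replicate 1, 7 without WT replicate 2, 0 without WT replicate 3, 1 without WT replicate 4, 3 without Xbp1KO replicate 1, 1 without Xbp1KO replicate 2 and 0 with WT replicate 4 and Xbp1KO replicate 2, the libraries with neutrophil transcripts, both left out. The proliferation median was 0.932 with both left out, against -1.49 for erythroid and -0.229 for B progenitor markers, and from 0.843 to 1.29 with a single library left out. In each of the 4 pairs of an Xbp1KO and a WT library of batch 2, 26 to 30 of the 30 members were higher in Xbp1KO. Ribosomal proteins had a median of 0.64 with 2 of 85 past the test, Rpl27a (1.08 ± 0.23) and Rpl4 (0.93 ± 0.22), and 0 adjusted over the list alone (camera adjusted p = 6.82e-10, adjusted p = 0.755 with an estimated correlation, and 0.239 by fry). Ribosomal genes past the test numbered 21 without Blimp1KO replicate 1, 37 without Blimp1KO replicate 2 and 0 without any other library.

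Stress genes split. With WT replicate 3, WT replicate 4, Xbp1KO replicate 1 or Xbp1KO replicate 2 left out, the counts of called stress, survival and sterol genes given here each lay between 0 and 2, and without Blimp1KO replicate 2 up to 6 sterol genes fell. Of 18 ATF4 integrated stress response targets, the serine synthesis enzyme Psat1 (1.497 ± 0.23) and the transcription factor Atf5 (1.60 ± 0.28) rose and 0 fell (6 rose adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.0173, adjusted p = 0.488 with an estimated correlation, and 0.0577 and 0.0511 at the preset correlation without WT replicate 4 and without Xbp1KO replicate 1). Of 13 UPR transducers and transcription factors, Atf6b (-1.59 ± 0.16) and Eif2ak3, which encodes the kinase PERK (-1.45 ± 0.21), fell, the same 2 calls adjusted over the list alone (camera adjusted p = 0.182). RIDD substrates had 2 of 6 lower by either adjustment, Hgsnat (-2.59 ± 0.32) and Bloc1s1 (-2.29 ± 0.51, 55.9% of its exon bases shared with Rdh5), with a camera adjusted p of 0.0528. In amino acid transport and mTORC1, Slc1a5 (-1.13 ± 0.19) and Rragd (-1.79 ± 0.30) were the 2 of 25 that fell by either adjustment (camera adjusted p = 0.139). In BCL2 family and apoptosis, Bcl2l1 (1.32 ± 0.18), Bid (0.95 ± 0.16) and Bak1 (0.89 ± 0.17) rose among 26 members (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.137). In sterol and fatty acid synthesis, 3 of 28 rose, with Sqle at 1.57 ± 0.22, and 2 fell, Insig1 (-1.95 ± 0.24) and Cyp51 (-0.77 ± 0.13), or 3 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.730).

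B cell genes did not move as a group in Xbp1KO. Without WT replicate 3 or 4, 0 genes of the B cell list, the class II list or the plasma cell list were called higher, and without Blimp1KO replicate 2 these numbered 4, 2 and 3. In mature B cell identity, Cd40 (1.51 ± 0.27) and the complement receptor Cr2 (2.19 ± 0.42) rose and Fcrla (-3.34 ± 0.28) and Irf8 (-0.86 ± 0.20) fell among 35 members (2 higher and 3 lower adjusted over the list alone), and the median of 0.31 went against camera's downward direction (adjusted p = 0.839). In MHC class II antigen presentation, H2-Eb2 (1.21 ± 0.19) and H2-DMa (1.20 ± 0.21) rose among 12 members (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.742). In plasma cell identity and surface, the checkpoint receptor Lag3 (-2.95 ± 0.33) fell and Epcam (1.68 ± 0.25) and S1pr1 (1.89 ± 0.39) rose among 27 (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.839). Cstf2, a cleavage factor of mRNA ends, was the 1 of 9 immunoglobulin mRNA processing factors that rose by either adjustment (0.91 ± 0.15, camera adjusted p = 0.227). Cstf2, Irf7 and Psmd14 each lost their call without WT replicate 1, 2, 3 or 4 and without Xbp1KO replicate 1 or 2. Among interferon-stimulated genes, Isg20 (-2.65 ± 0.26) fell and Irf7 (0.73 ± 0.17) rose of 25 (1 higher and 2 lower adjusted over the list alone), and the median of 0.43 went against camera's downward direction (adjusted p = 0.730). Mitochondrial oxidative phosphorylation had 1 of 73 higher, Cox6a2 (0 adjusted over the list alone, camera adjusted p = 0.100), and the proteasome 1 of 38, Psmd14 at 0.67 ± 0.16 (0 adjusted over the list alone, camera adjusted p = 0.267).

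Markers of other cells gave no camera call in Xbp1KO from all 8 libraries, and with WT replicate 4 and Xbp1KO replicate 2 both left out 0 of these markers were called by edgeR. Of 24 neutrophil and monocyte markers, Itgam rose by 1.88 ± 0.32 (1 call by either adjustment, with 68.7% of its exon bases shared with Gm49368), and the median of 1.27 went against camera's downward direction (adjusted p = 0.756). Of 16 erythroid and megakaryocyte markers 0 passed by either adjustment (Pf4 5.27 ± 2.12, Itga2b 1.41 ± 0.58, camera adjusted p = 0.756), while 16 of 16 estimates were higher, with a median of 1.49 that was -3.70 without Xbp1KO replicate 2. Of 22 T and NK markers Cd8b1 rose (3.24 ± 0.52, 1 call by either adjustment, camera adjusted p = 0.414). Of 14 dendritic markers Ccr9 (1.53 ± 0.23) and Cox6a2 rose and Pacsin1 (-1.99 ± 0.35) fell, the same numbers adjusted over the list alone (camera adjusted p = 0.354). Of 13 stroma and endothelium markers Alpl rose (1.38 ± 0.13, 1 call by either adjustment, camera adjusted p = 0.839). Of 13 B progenitor markers Kit (1.56 ± 0.30) and Myb (1.42 ± 0.31) rose, 2 calls by either adjustment (camera adjusted p = 0.0886), and 12 of 13 estimates were higher, with a median of 1.42 that was 0.0596 without Xbp1KO replicate 2. These 2 calls numbered 0 without WT replicate 1, 2, 3 or 4 and without Xbp1KO replicate 2. The 2 higher dendritic calls numbered 0 without WT replicate 3, WT replicate 4 or Xbp1KO replicate 1 and 1 without Xbp1KO replicate 2, and the lower one 0 without any one WT or Xbp1KO library. The neutrophil call ended without WT replicate 3, Xbp1KO replicate 1 or Xbp1KO replicate 2, and T and NK calls numbered 0 without WT replicate 4 and 2 without WT replicate 3, Blimp1KO replicate 1 or Blimp1KO replicate 2. Without Xbp1KO replicate 1 camera called neutrophil (adjusted p = 9.1e-08), erythroid (4.72e-06), B progenitor (7.68e-07), T and NK (0.00491) and dendritic (0.00853) markers upward. It called neutrophil markers downward without WT replicate 3 (0.00282), and neutrophil (0.0146) and erythroid (0.0355) markers downward without Xbp1KO replicate 2.

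The effects of the knockouts were compared by the difference between them. It passed the test for 253 genes, 176 with a higher and 77 with a lower effect in Blimp1KO. A higher effect can also be a smaller fall than in Xbp1KO. The 5 highest differences were those of Nucb2 (5.80 ± 0.64, adjusted p = 0.0141), Pigr (4.97 ± 0.60), Ltb (4.87 ± 0.46), Hid1 (4.73 ± 0.23) and Napsa (4.002 ± 0.31). The 5 lowest were those of Tsc22d1 (-5.33 ± 0.49), Slc7a3 (-5.06 ± 0.34), Atp1b1 (-4.12 ± 0.69), Kit (-3.43 ± 0.43) and Hsd11b1 (-3.36 ± 0.42). Bcl2l1 fell in Blimp1KO and rose in Xbp1KO, with a difference of -2.75 ± 0.25, and Alpl did likewise with -2.99 ± 0.19. By list, 6 of 12 MHC class II genes and 7 of 29 ER chaperones had a higher effect in Blimp1KO, and 4 of 30 proliferation genes a lower effect. The camera adjusted p was 7.34e-09, 4.03e-05 and 9.43e-15, with adjusted p = 0.518, 0.821 and 0.675 with an estimated correlation. Camera also called mature B cell identity, ER translocation and ER-Golgi vesicle transport (each upward, adjusted p = 4.03e-05, and 0.518, 0.675 and 0.799 with an estimated correlation) and N-glycosylation (upward, adjusted p = 0.0102, and 0.887 with an estimated correlation). Downward calls were those of ATF4 integrated stress response targets (adjusted p = 0.000101, and 0.518 with an estimated correlation) and B progenitor markers (adjusted p = 0.0183, and 0.887 with an estimated correlation). By fry the adjusted p of the lists called here lay from 0.0823 (MHC class II and ER chaperones) to 0.53 (B progenitor markers). The fits with libraries left out share most libraries with the fit that picked the 253 genes. The count of 253 was 9 without WT replicate 1, 3 without WT replicate 2, 32 without WT replicate 3, 47 without WT replicate 4, 598 without Blimp1KO replicate 1, 506 without Blimp1KO replicate 2, 68 without Xbp1KO replicate 1, 114 without Xbp1KO replicate 2, and 2 without both WT replicate 4 and Xbp1KO replicate 2, and all 253 differences kept their sign in these fits.

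The overlap of the knockouts was small in number and above that of independent lists. Both contrasts use the same estimate of a gene's spread, so the lists would not be independent even without a shared effect. Batches fitted alone, a count chosen after the data were seen, shared 1 gene. In both, 11 genes rose, against 2.29 for independent lists (Fisher's exact p = 1.71e-05 across genes, which are not independent replicates), among them S1pr1, Cd40, H2-DMa and Vim. In both, 14 fell, against 2.18 (Fisher's exact p = 1.28e-08), among them Hist1h1c, Clec2g, Thbd, Sema6d and some heavy chain variable segments. A further 11 went opposite ways, against 5.54, among them Bcl2l1, Alpl, Hsd11b1 and Napsa. Of the 763 genes lower in Xbp1KO, 78.1% had a lower estimate in Blimp1KO, against 50.5% of all genes tested, and of the 397 higher, 53.2% had a higher estimate against 48.8%. Across genes, Pearson's r between the effects was 0.110 and Spearman's rho 0.138. Of these genes Vim and Sema6d were chosen after their values were seen. The 25 shared genes numbered 0 without WT replicate 1, 2, 3 or 4, 142 without Blimp1KO replicate 1, 59 without Blimp1KO replicate 2, 14 without Xbp1KO replicate 1 and 10 without Xbp1KO replicate 2.

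**Figure D5:**
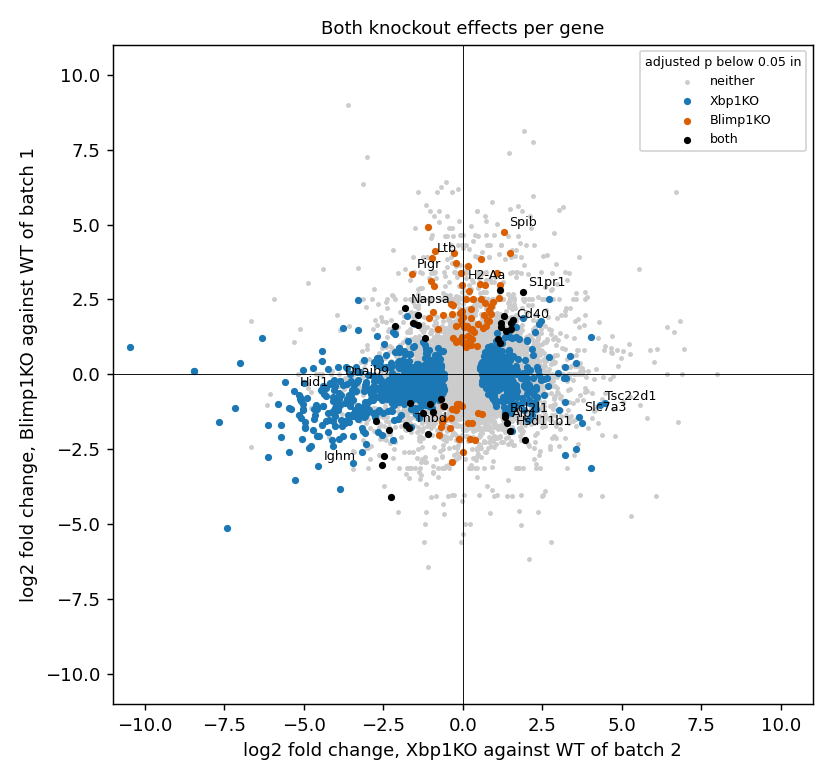
Log2 fold change of each gene tested in Xbp1KO against WT of batch 2 (horizontal) and in Blimp1KO against WT of batch 1 (vertical), coloured by the test each gene passed. Spib and Ltb lie high near the vertical axis, Hid1 and Dnajb9 far to the left near the horizontal axis, and S1pr1 and Cd40 are among the 11 genes higher in both.

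WT libraries differed between batches at 423 genes, 296 higher and 127 lower in batch 2, of which 169 were pseudogenes or predicted genes. Of 15 genes of the mitochondrial genome, 5 were higher in batch 2 and 0 lower. Of 85 ribosomal proteins, 6 were higher and 8 lower. Without immunoglobulin genes the split was 341 higher and 82 lower. The count was 14 without WT replicate 1, 39 without WT replicate 2, 28 without WT replicate 3, 28 without WT replicate 4, 2141 without Blimp1KO replicate 1, 2963 without Blimp1KO replicate 2, 213 without Xbp1KO replicate 1 and 241 without Xbp1KO replicate 2. Batch and any difference between the WT mice cannot be told apart.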

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

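The difference between the knockout effects was planned, and every test of an explanation below was chosen only after the result it concerns was seen. In all, 253 genes had effects that differed between Blimp1KO and Xbp1KO by edgeR's interaction contrast with Benjamini-Hochberg adjustment, and named genes among them are given as the log2 effect in Blimp1KO minus that in Xbp1KO.

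Higher effects in Blimp1KO were those of Nucb2 (5.80), Pigr (4.97), Ltb (4.87), Hid1 (4.73), Napsa (4.002), Rdh12 (3.95), Kcnk6 (3.87), Dnajb9 (3.66), Plac8 (3.46), Fcrla (3.42), Atat1 (3.20), H2-Aa (3.02), Erp44 (2.81), Fkbp11 (2.78), H2-Eb1 (2.40), Dnajc3 (2.27), H2-Ob (2.18), Rpn1 (2.16), Scd1 (2.14), Ero1lb (2.10), Kdelr3 (1.60), Bet1 (1.36), Atf6b (1.31) and Mcfd2 (1.27). Lower effects in Blimp1KO were those of Gadd45b (-1.40), Sqle (-1.83), Top2a (-2.40), Chac1 (-2.58), Psat1 (-2.58), Kif11 (-2.75), Bcl2l1 (-2.75), Gsto1 (-2.91), Cd36 (-2.95), Alpl (-2.99), Dpp4 (-3.06), Bub1 (-3.27), Hsd11b1 (-3.36), Kit (-3.43), Cr2 (-3.53), Atp1b1 (-4.12), Slc7a3 (-5.06) and Tsc22d1 (-5.33). A higher effect need not be a rise in Blimp1KO, nor a lower effect a fall. Hid1 had -0.57 in Blimp1KO and -5.30 in Xbp1KO, and Dnajb9 -0.21 and -3.87, while Ltb had 3.90 and -0.98. Cd36 had 0.26 in Blimp1KO and 3.21 in Xbp1KO. The batches and the WT mice differ along with the knockouts.

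Of MHC class II genes 7 of 12, and of B cell genes 4 of 35, were called higher in Blimp1KO by edgeR, and 0 of either without WT replicate 1, 2, 3 or 4, where the medians lay from 1.68 to 2.47 and from 0.912 to 1.13. WT replicates 3 and 4 are of batch 2 and act here only through the shared spread, the filter and the scaling. The fit of batch 1 alone called 0 and 5. Camera's adjusted p was 0.211 for both lists with an estimated correlation, and fry's was 0.0258 for class II and 0.0729 for B cell genes. IgD-positive mature B cells as the source are argued against by Ighd, which had a log2 fold change of -3.08 (SE 0.587) and 2.49 ± 0.0119 CPM (SD, n = 2) in Blimp1KO, while H2-Aa reached 2522 ± 415 CPM. Scaling, which shifts all genes of a library alike, would by itself leave the class II median at that of all genes, and it lay 2.04 (SE 0.476) above. This restates the observed rise and is no separate test. The SE treats the list's genes as independent, while their estimated correlation was 0.418. Dendritic cells stay open, since 11 of 14 of their markers had higher estimates (median 0.759). B cells without IgD stay open: of 21 members of the B cell list below 30 CPM in WT of batch 1, 90.5% had a higher estimate, which such cells and a B cell programme kept by the sorted cells would both give. The sort on Blimp1-GFP and CD138 is meant to select against both dendritic and B cells.

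The share of immunoglobulin counts was lower in both knockouts. RNA of other cells would lower transcripts found in plasma cells alone by the same factor. The median log2 ratio of the plasma cell list's shares was 0.557 (SE 0.197) in Blimp1KO against -0.412 for immunoglobulin, and 1.33 (SE 0.245) in Xbp1KO against -1.29. This list does not decide: not all members mark plasma cells alone (Cd93 is also on the B progenitor list), and the SE treats the members as independent. The J chain's share had log2 ratios of -0.034 in Blimp1KO and 0.437 in Xbp1KO. Dilution alone would have lowered it by the factor of the immunoglobulin share. These values argue against RNA of cells that lack J chain as the sole cause, though they rest on a single gene. Depth is argued against in Xbp1KO by the difference in share from WT with log2 total count as a covariate over all 8 libraries, -37 (SE 1.07) percentage points. The same fit, with 3 residual degrees of freedom, gave -18.4 (SE 0.947) in Blimp1KO. Totals of the batch 1 groups differed little, so the covariate could hardly change that difference. Batch is left out by comparing each knockout with WT of its own batch. RNA of other cells as part of the cause, clones and a lower output of immunoglobulin transcripts by the sorted cells stay open. Counts relative to a library's total do not measure output per cell, and a measurement per cell would decide.

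Proliferation genes were higher in Xbp1KO, by 12 calls in edgeR that fell to 0 without WT replicate 3, 1 without WT replicate 4, 3 without Xbp1KO replicate 1, 1 without Xbp1KO replicate 2 and 0 with WT replicate 4 and Xbp1KO replicate 2 both left out. The median of 1.16 was 0.932 with both left out and from 0.843 to 1.29 with a single library left out, and 26 to 30 of 30 members were higher in each pair of an Xbp1KO and a WT library of batch 2. Markers of dividing marrow cells had higher estimates too, 16 of 16 for erythroid cells (median 1.49) and 12 of 13 for B progenitors (median 1.42). These medians were -3.70 and 0.0596 without Xbp1KO replicate 2, and -1.49 and -0.229 with both left out. The list's mean log2 CPM was 1.05 (SE 0.318) higher in Xbp1KO over all 8 libraries. Neutrophil or erythroid precursors as the whole cause are argued against by what was left with their markers' mean as a covariate, 1.04 (SE 0.23) and 0.99 (SE 0.167), each beyond the t limit of 3.18 SE. B progenitors stay open: with their markers as a covariate it was 0.718 (SE 0.288), within that limit, and 0.549 (SE 0.163) on the CPM scale, beyond it. Scaling by itself would leave the list's median at that of all genes, and it lay 1.08 (SE 0.109) above. This too restates the observed rise, and the SE treats genes with an estimated correlation of 0.622 as independent. A larger share of dividing plasmablasts cannot be told apart from division of the plasma cells: class II genes, which plasmablasts keep, had a median of -0.151 with members going both ways.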

How the results depend on the processing

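The replicate block in both batches, the removal of WT replicate 4 with Xbp1KO replicate 2, the batch 1 block for the difference of effects and the number shared by batches fitted alone were chosen only after the data were seen. The counts computed from all 8 libraries were 130 genes for Blimp1KO, 1160 for Xbp1KO, 253 for the difference of effects, 423 for WT between batches and 25 for both knockouts. In that order of comparisons, without a filter they were 517 for Blimp1KO, 763 for the difference, 1662 for WT and 140 for both. The stricter filter gave 261 for Blimp1KO, 394 for the difference and 71 for both. A threshold of 1.5-fold gave 14, 418, 104, 158 and 1, DESeq2 on 23678 genes, without the filter, gave 813, 2172, 1156, 1986 and 263, and limma-voom gave 83 for Blimp1KO and 204 for WT. The FPKM gave 48 for both. Batches fitted alone gave 20 for Blimp1KO and 1 for both, and pooled WT gave 269 and 40. Without WT replicate 4 and Xbp1KO replicate 2 the counts were 31, 59, 2, 32 and 0. With a single library left out they ranged from 0 to 688, 225 to 2123, 3 to 598, 14 to 2963 and 0 to 142, and Xbp1KO lists called by camera from 8 to 16 against 9. The lowest and highest were without WT replicate 1 (0) or 2 (0) and Blimp1KO replicate 1 (688) for Blimp1KO, without WT replicate 3 (225) and Blimp1KO replicate 2 (2123) for Xbp1KO, without WT replicate 2 (3) and Blimp1KO replicate 1 (598) for the difference, without WT replicate 1 (14) and Blimp1KO replicate 2 (2963) for WT, and without Blimp1KO replicate 1 (142) for both. The lone library left in a group was assumed to vary like the other groups. A library of the other batch enters a knockout's contrast through the shared spread, the filter and the scaling, not through the group means. Beyond this, the cause was not tested for any of these.

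The replicate number as a block in batch 1 gave 89 genes for Blimp1KO, 1021 for Xbp1KO and 178 for the difference, and blocks in both batches 164, 1169, 386 and 44 for both knockouts. No pairing is stated. WT and Blimp1KO of batch 1 share the numbers 1 and 2, while in batch 2 the labels give WT 3 and 4 and Xbp1KO 1 and 2, and the block there took WT 3 with Xbp1KO 1 and WT 4 with Xbp1KO 2 from the numbers in the file names. Differences between replicates correlated across genes at r 0.218 between the groups of batch 1 and 0.513 between those of batch 2.

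List medians whose sign or camera direction turned belonged to lists not called from all 8 libraries. For Blimp1KO, oxidative phosphorylation was 0.432 without Blimp1KO replicate 1, from -0.417 to 0.432 over single libraries, and 0.372 with pooled WT. Immunoglobulin mRNA processing ranged from -0.0984 to 0.236 and the proteasome from -0.201 to 0.358. Neutrophil markers were -0.528 without WT replicate 4 and Xbp1KO replicate 2, -0.611 with blocks in both batches, and -1.04 to 0.0248 over single libraries. For Xbp1KO, interferon-stimulated genes ranged from -0.832 to 0.715, neutrophil markers from -6.58 to 6.63 with 2.18 without Xbp1KO replicate 1 and 0.349 with blocks in both batches, and erythroid markers from -3.70 to 3.89. The cause was not tested. Of other results, 3592 kept their direction and side of the threshold, 581 lost the threshold, 102 gained it, 104 moved and 10 reversed, summed over settings. Simulated 2-fold changes were recovered for 3 and 8 of 100 genes, so small effects can be missed. The simulation changed fewer genes than edgeR called in Xbp1KO, which makes the adjusted threshold stricter. Its rates need not hold in that contrast, where 832 of the 1160 called genes were past 2-fold and the others below it.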

Other observations

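The comparison of heavy and kappa chain segments below was chosen only after the values were seen, and the marker lists were fixed in advance. In Xbp1KO the 118 heavy chain variable segments had a median log2 fold change of -3.81 (quartiles -4.67 and -3.07) and the 102 kappa variable segments -1.92 (quartiles -2.68 and -0.994), a difference of -1.89. In Blimp1KO the medians were -1.38 and -0.976, a difference of -0.399. Without Blimp1KO replicate 2 that order turned, to -1.37 and -1.42. In Xbp1KO the order held in every setting run, with -3.94 and -1.61 without WT replicate 4 and Xbp1KO replicate 2. Whether heavy chain transcripts depend on XBP1 more than kappa transcripts stays open: the comparison was prompted by these values, and segments share reads and follow clones.

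Transcripts that tell the sexes apart differed between libraries of one group. Xist had 2.52 and 16.9 CPM in WT of batch 1, 2.61 and 7.26 CPM in Blimp1KO, 387 and 272 CPM in WT of batch 2, and 343 and 594 CPM in Xbp1KO. Ddx3y, on the Y chromosome, had 43.3, 30.6, 48.1, 15.4, 0.0427, 33.4, 45.8 and 19.6 CPM in the same order. WT replicate 3 thus had Xist and almost no Ddx3y, and the other 3 libraries of batch 2 had both. The labels do not state the sex or how many mice went into a library.

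Neutrophil and erythroid transcripts were also present in batch 1. S100a8 had 22.1 and 44.4 CPM in WT and 12.0 and 30.9 CPM in Blimp1KO, Lyz2 had 170, 157, 345 and 109 CPM, and Hba-a2 had 13.4, 59.0, 12.6 and 67.8 CPM in that order. In batch 2, Ngp had 0.606 and 93.6 CPM in WT and 0.0588 and 238 CPM in Xbp1KO, and Slc4a1 had 2.28, 47.8, 0.588 and 153 CPM.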
